A study of Homo sapiens with 9 samples.

How the data were processed

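Gene expression was measured on 9 single-colour Affymetrix arrays of the human breast cancer line MCF7aro, an established MCF-7 derivative that carries an aromatase gene and is estrogen receptor positive. Per the labels, 3 arrays held control cells without exemestane after 48 h in hormone-stripped medium, 3 held cells treated intermittently with 1 µM exemestane (2 weeks on and 1 week off) for 14 weeks, and 3 held cells treated continuously with 1 µM exemestane for 14 weeks. Both treated groups were grown with 1 nM testosterone, which the labels do not name for the control. The labels name the 48 h of stripping for the control, and the wording of their protocol leaves unclear whether treated cells had it before harvest. The labels do not say whether the intermittent cells were collected in a week on or off the drug, and nothing says that the replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

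The authors deposited 1 table of processed values for the 9 arrays, with 33297 rows. Its values are an intensity on a linear scale, as the deposited values themselves show, and each array's median lay between 97.2 and 104.6. Affymetrix Expression Console is named in the submitters' processing notes, and its version, summarization method and scaling are not given in the sources used here. Between 335 and 559 rows per array were listed at 0. The annotation given with the table is that of an Affymetrix whole-transcript Human Gene ST array, and the labels' labelling protocol is also for whole-transcript arrays, while the labels' treatment protocol names another Affymetrix expression array. The annotation was used because its row identifiers matched the table. It named 1 gene for 19460 rows, several genes for 1754 and none for 12083, and 31 of the rows with 1 symbol did not match the gene table by gene identifier. Rows with several genes or none were left out of the tests per gene. For the 769 genes with several rows, the row with the highest mean over the 9 arrays was used, which left 18417 genes. Every column was matched to 1 sample by its label.

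The design fixed before the data were examined called for log2 of the values. The zeros have no log, so log2(value + 16) was used, and all fold changes are on that scale, which understates the change of dim genes. No detection calls were used, so a value near 0 is reported as a value and not as absence of the transcript. A single linear model with 3 group means was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and 3 comparisons were drawn from it with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. A test across the 3 groups (the moderated F) was taken from the same fit. The number of arrays limits the precision. In simulated data on the 18417 genes, 200 genes were changed, all drawn from those brighter than the median. For intermittent against control, 24% of the 1.5-fold and 90% of the 2-fold changes were recovered, with 4 false calls among 161. For continuous against control these were 20% and 94%, with 11 false calls among 167, and for intermittent against continuous 22% and 90%, with 10 false calls among 166.

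Gene lists were fixed before the data were examined, 27 in all: estrogen-induced, estrogen-repressed, luminal identity, androgen targets, steroid metabolism, ERBB ligands and receptors, MAPK output, PI3K and IGF signalling, mitosis, DNA replication, p53 targets, BCL2 family, autophagy and lysosome, unfolded protein response, cholesterol synthesis, fatty acid synthesis, interferon response, MHC class I, NF-kB cytokines, mesenchymal, basal and progenitor, hypoxia and glycolysis, xenobiotic and oxidative response, drug efflux, immediate early genes of handling, and markers of immune cells and of stromal and endothelial cells. Each list was tested with limma's camera with a preset correlation of 0.01, adjusted over the 27 lists of a comparison, beside camera with an estimated correlation and fry. Camera asks whether a list's genes shifted relative to the other genes, and fry whether they shifted at all, so their calls answer different questions. Counts of members are given over all genes tested and adjusted over the list alone. Listed genes without a row of their own were not measured. Missing were HMGCR, LDLR, FDFT1, DHCR24 and PCSK9 in cholesterol synthesis. Others were TMPRSS2 and NKX3-1 in androgen targets and KRT17, KRT6A, KRT6B and TP63 in basal and progenitor genes.

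The genes named were fixed by rule. They are the 10 genes with the largest rise and the 10 with the largest fall in each comparison, among called genes whose 3 values in 1 group all lay above the 3 in the other. To these come up to 4 called members of each list described, those with the smallest adjusted p, and CYP19A1, ESR1, PGR, GREB1, TFF1, AR, AREG, EGFR, ERBB2, CCND1, MKI67, BCL2 and FKBP5 whatever their test said. Uncharacterised loci and small RNA genes were passed over. AR and AREG had no row of their own in the annotation and FKBP5 only 2 rows shared with other genes, so none of the 3 has a value here.

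Alternatives were a block for the replicate numbers, quantile normalization, median centring, leaving out the dimmest genes (1 in 3), the mean of a gene's rows, all rows, eBayes with trend and robust options, array weights, leaving out each array in turn, fitting only the 6 arrays compared, a 2-fold minimum and limma's treat against a 1.2-fold change. Offsets of 1 and 50, a floor of 16 and zeros set to the smallest value above 0 were added after seeing the data. To look at the effect of the shared control arrays, 100 simulations were run in which no gene changed. In each, both treated groups were compared with the same 3 simulated controls. For checks along the genome, genes were put in the order of the RefSeq annotation of GRCh38.p14. The array's own genome build is not given in the sources used here, so no coordinates were taken. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.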

Results

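Expression profiles of MCF7aro cells were compared between 3 control arrays, 3 arrays of cells given exemestane intermittently for 14 weeks and 3 arrays of cells given it continuously for 14 weeks. Exemestane is a steroidal inhibitor of aromatase, the enzyme that makes estrogen from androgens such as the testosterone in the treated cultures. The series asks how the 2 dosing schedules differ in acquired resistance to the drug. Of the 18417 genes tested, 4424 differed among the 3 groups (limma, moderated F, adjusted p under 0.05). Correlations of log2 values across genes, which are not independent replicates, were 0.967 to 0.982 within groups and 0.926 to 0.960 between groups. Errors below are SD of the deposited intensities, with n = 3 arrays per group, and folds are on the log2(value + 16) scale, so the size and rank of a change in a gene with values near or below 16 depend on that offset. The androgen receptor gene AR, AREG and FKBP5 had no value.

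The first comparison asks how cells kept on intermittent exemestane with testosterone differ from control cells, for which the labels name neither. Classical estrogen-responsive genes were far higher in the intermittent cells. PGR, the progesterone receptor, stood at 823.7 ± 82.5 against 35.6 ± 9.74 in control (16.4-fold, limma adjusted p = 4.73e-07). GREB1, a coregulator induced by estrogen, was 4.64-fold higher (limma adjusted p = 3.13e-06), and TFF1, a secreted trefoil peptide, was 6.29-fold higher (limma adjusted p = 1.77e-05). DIO2, a deiodinase that activates thyroid hormone, fell from 3424 ± 169.7 to 12.2 ± 1.01, or 122-fold on this scale (limma adjusted p = 2.14e-09). Its log2 change of -6.93 ranged from -8.13 to -5.80 over the alternatives. Of the interferon-response list 15 of 28 members were called lower than in control, and of the mesenchymal list 5 of 13. Neither list passed camera with an estimated correlation (adjusted p = 0.692 and 0.123).

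In all, 3739 genes changed between intermittent and control cells, of which 1521 rose and 2218 fell (limma, adjusted p under 0.05). A change of at least 2-fold was seen for 836 of them and of at least 4-fold for 146. The 10 genes that rose most were PKIB (22.9-fold), an inhibitor of protein kinase A, GJA1 (19.0-fold), which encodes a gap junction connexin, PIP (18.0-fold), PGR, F13A1 (15.7-fold), a coagulation factor subunit, the kallikrein protease KLK11 (15.5-fold), the neuropeptide Y receptor NPY1R (12.9-fold), TXNDC8 (12.7-fold), the matrix protein MGP (11.8-fold) and TMEM164 (10.2-fold). Control values of PIP and TXNDC8 were near 0, with 1 and 2 of the 3 control arrays listed at 0. PIP lost its call when zeros were set to the smallest value above 0, the single setting that ended it (limma adjusted p = 0.0645). After DIO2, the largest falls on this scale were in the smooth muscle actin ACTG2 (35.6-fold), the protocadherin PCDHB2 (21.96-fold), EDIL3 (18.6-fold), the actin-bundling protein PLS3 (17.4-fold), N-cadherin CDH2 (13.4-fold), the collagen COL4A3 (11.6-fold), caldesmon CALD1 (11.4-fold), the noncoding RNA LINC00052 (11.1-fold) and the actin-severing protein SCIN (10.7-fold). LINC00052 also lost its call with zeros at the smallest value above 0 (limma adjusted p = 0.059).

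The rise of hormone-responsive genes held across the estrogen-induced list. Of its 31 measured members 24 rose and 1 fell, or 27 and 1 adjusted over the list alone, with a median log2 change of 1.22 (camera adjusted p = 1.06e-22, and adjusted p = 0.0133 with an estimated correlation). PKIB and PGR led it, followed by RAPGEFL1 (7.43-fold) and the transcription factor MYBL1 (7.40-fold). In the estrogen-repressed list 8 of 12 members fell and none rose, with the same counts adjusted over the list alone (camera adjusted p = 0.000178, but adjusted p = 0.34 with an estimated correlation). BMF, a BH3-only promoter of apoptosis, fell 5.24-fold and TGFB2, a growth factor, fell 2.39-fold. ERBB2 fell 1.65-fold (limma adjusted p = 0.00394) and EGFR 1.78-fold (limma adjusted p = 0.00496). CYP19A1, the aromatase gene, measured 3129 ± 269.1 in intermittent cells and 5316 ± 15.5 in control, a log2 change of -0.77 (limma adjusted p = 0.00239). MCF7aro carries an aromatase gene besides the cells' own, and these values do not separate the 2. ESR1, the estrogen receptor gene, did not pass the test at 812.0 ± 106.5 against 722.1 ± 29.2 (limma adjusted p = 0.43), nor did BCL2 at 535.7 ± 182.7 against 327.6 ± 15.9 (limma adjusted p = 0.0657). CCND1, which encodes cyclin D1, was 1.28-fold higher (limma adjusted p = 0.048), and this call ended without any 1 of the 9 arrays, with limma adjusted p from 0.0523 to 0.119, with median centring (0.0838) and with array weights (0.058). MKI67, a proliferation marker, was 1.39-fold lower (limma adjusted p = 0.0323). Its call ended without any 1 control array (0.0888, 0.0618 and 0.0819 for replicates 1 to 3), intermittent replicate 3 (0.0708) or continuous replicates 1 (0.0516) or 3 (0.0524), all limma adjusted p. Other mitosis genes went the other way: AURKA and BIRC5 rose (log2 0.66 and 0.64, limma adjusted p = 0.00827 and 0.00863) and kept their calls without each array. The mitosis list had a median log2 change of 0.21 and did not pass camera.

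Interferon-response genes were lower in the intermittent cells: 15 of 28 members fell and 1 rose, or 23 and 1 adjusted over the list alone, with a median log2 change of -1.07 (camera adjusted p = 5.5e-07, but adjusted p = 0.692 with an estimated correlation). OASL fell 2.83-fold, MX2 2.70-fold and CMPK2 3.60-fold, while IFI27 rose 2.55-fold (limma adjusted p = 0.000582). Intermittent replicate 3 stood apart in this list, with a mean of -1.36 relative to the 9-array mean, against -0.37 and -0.24 in the other intermittent arrays and 0.26 to 0.33 in control. Without it the median change was -0.62. In the antigen presentation list (MHC class I), where no HLA gene had a row of its own, 4 of 8 members fell, TAP2, ERAP1, TAPBP and TAP1, and adjusted over the list alone 5 fell and 1 rose. Its call (camera adjusted p = 0.0299, adjusted p = 0.692 with an estimated correlation) ended without intermittent replicate 2 (camera adjusted p = 0.0533). A shift shared with neighbouring genes in the genome was not tested for this list.

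Of the mesenchymal list 5 of 13 members fell and none rose, with the same counts adjusted over the list alone (median log2 change -0.33, camera adjusted p = 0.00187, adjusted p = 0.123 with an estimated correlation). Without the dimmest genes the median was -0.80 (camera adjusted p = 0.0258). CDH2 fell 13.4-fold, and the transcription factors TWIST1 and SNAI2 fell 3.72-fold and 4.97-fold. Fibronectin, FN1, fell 2.41-fold. The cholesterol synthesis list was called higher, with 3 of 18 members up and none down, or 7 and none adjusted over the list alone (median 0.47, camera adjusted p = 0.000956, adjusted p = 0.716 with an estimated correlation). CYP51A1, a sterol demethylase, was 2.29-fold higher. This call ended without intermittent replicate 2 (camera adjusted p = 0.0533), and without intermittent replicate 3 the median was 0.76. That array showed no rise: its list mean relative to the 9 arrays was -0.48, against 0.25 and 0.48 in the other intermittent arrays and -0.48 to -0.37 in control.

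The other 21 lists did not pass camera in this comparison, although single members changed. Of these, fry called the BCL2 family (6.18e-05), androgen targets (0.00052), immediate early genes (0.0101) and PI3K and IGF (0.0494). Fry did not call the interferon (0.0686) and cholesterol (0.143) lists that camera called, all fry adjusted p. XBP1, a secretory-pathway transcription factor, rose 5.01-fold and AGR2 rose 2.83-fold in the luminal identity list, where 3 members rose and 6 fell of 15. BAK1, a promoter of apoptosis, fell 6.05-fold and BCL2L11 fell 2.14-fold among 4 falls and no rise in the 15 genes of the BCL2 family. The zinc finger gene ZBTB16 rose 5.67-fold in the androgen target list (6 up and 2 down of 18), its call ending only with zeros at the smallest value above 0 (limma adjusted p = 0.0568). CYP1A1 fell 4.18-fold and AKR1C1 rose 3.45-fold in the steroid metabolism list (4 up and 4 down of 20), and TXNRD1 rose 2.75-fold in the xenobiotic and oxidative list (5 up and 3 down of 14). ABCG2, a drug efflux pump, fell 4.23-fold (efflux list, none up and 3 down of 10). IGF1R rose 1.93-fold and FOXO1 fell 1.90-fold in the PI3K and IGF list (6 up and 5 down of 18). IL6 fell 4.47-fold in the NF-kB list (1 up and 3 down of 17). Members up and down were 1 and 4 of 13 for ERBB ligands and receptors, 2 and 1 of 17 for MAPK output, 2 and 1 of 24 for mitosis, 7 and 1 of 27 for DNA replication, 1 and 2 of 18 for p53 targets and 0 and 4 of 18 for autophagy and lysosome. They were 1 and 4 of 18 for the unfolded protein response, 4 and 2 of 13 for fatty acid synthesis, 1 and 1 of 11 for basal and progenitor genes, 3 and 3 of 18 for hypoxia and glycolysis and 2 and 4 of 10 for immediate early genes. Immune markers gave 0 and 1 of 11 and stromal and endothelial markers 0 and 2 of 13. Adjusted over the list alone, the counts that differed were 8 and 2 for androgen targets, 5 and 4 for steroid metabolism, 8 and 6 for PI3K and IGF, 8 and 2 for DNA replication, 2 and 5 for the BCL2 family, 1 and 5 for autophagy, 6 and 2 for fatty acid synthesis, 3 and 4 for hypoxia, 3 and 3 for efflux and 2 and 6 for immediate early genes. For luminal identity the median log2 change (-0.19) and the mean (0.01) differed in sign, for drug efflux the median was 0.02 and the mean -0.23, and for hypoxia and glycolysis the camera direction was up with a median and mean of -0.01. The treated cells differed from control in testosterone and 14 weeks of culture as well as in the drug. The labels also leave unclear whether they had the 48 h of hormone stripping before harvest that the control had, so no change in this comparison or the next can be given to exemestane alone. The number of lists called was 6 and rose to 10 without intermittent replicate 3.

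**Figure D1:**
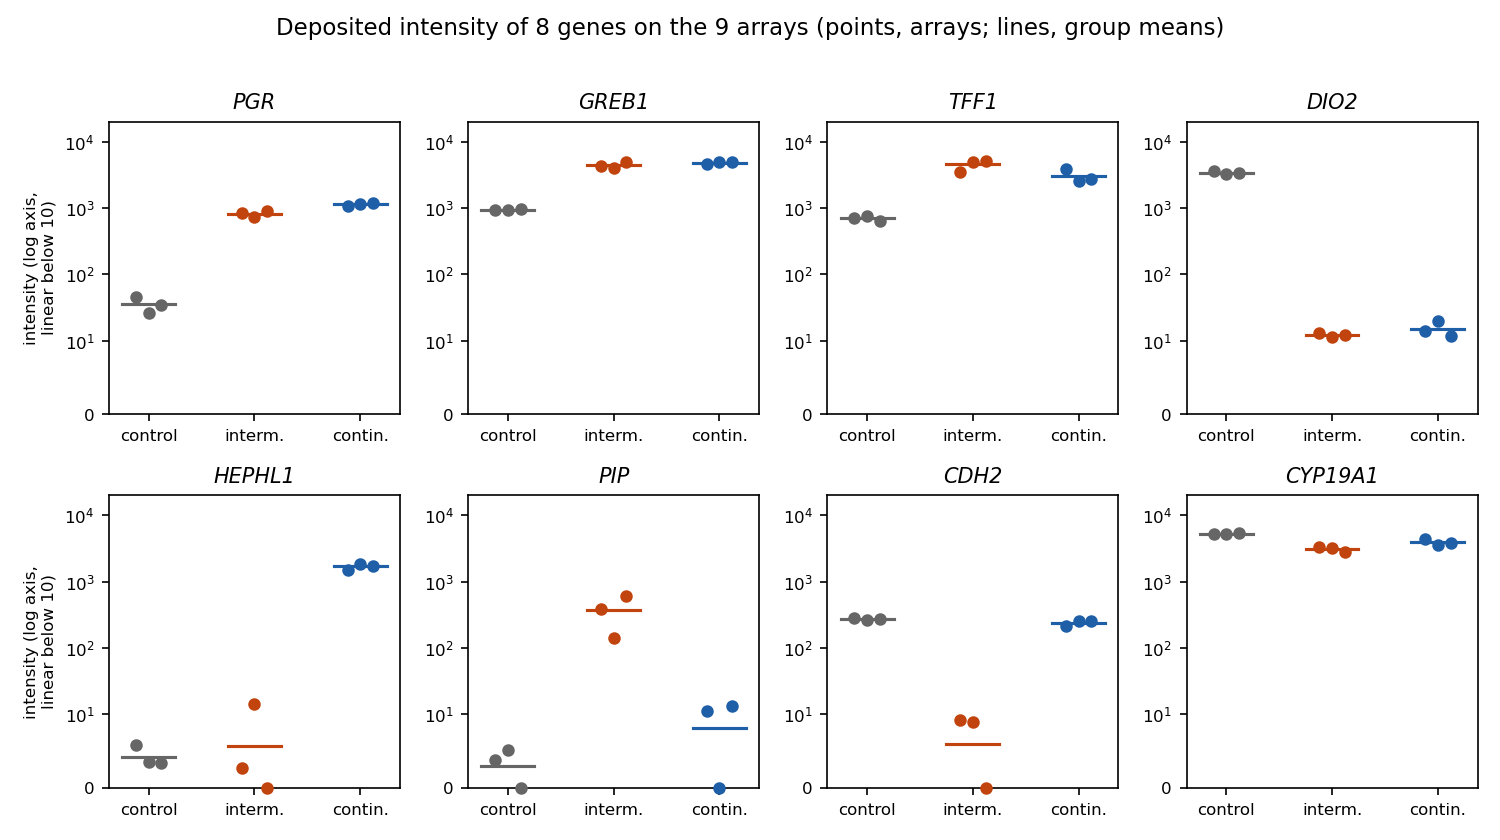
Deposited intensity (vertical axis, logarithmic above 10 and linear below) of 8 genes in the 3 control, 3 intermittent and 3 continuous arrays, with points for arrays and lines for group means. PGR, GREB1 and TFF1 are higher and DIO2 is lower in both treated groups, while HEPHL1 stands at 1703 in continuous cells alone, PIP is high in intermittent cells and CDH2 is low in them.

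The second comparison asks the same of continuous dosing, again with testosterone present in the treated cells. Estrogen-responsive genes rose here too. PGR stood at 1146 ± 51.9 against 35.6 ± 9.74 in control (22.8-fold, limma adjusted p = 1.85e-07), GREB1 was 5.03-fold higher (limma adjusted p = 4.41e-06) and TFF1 4.16-fold higher (limma adjusted p = 0.000173). HEPHL1, a ferroxidase-like gene, rose from 4.25 ± 1.34 to 1703 ± 170.4, 84.7-fold (limma adjusted p = 1.53e-07), and DIO2 fell 111-fold to 15.1 ± 4.28 (limma adjusted p = 2.6e-09). Called higher were 9 of 18 measured cholesterol synthesis genes and 4 of 13 fatty acid synthesis genes, and 7 of 17 genes of the NF-kB list were called lower. None of the 3 lists passed camera with an estimated correlation (adjusted p = 0.571, 0.522 and 0.522).

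In this comparison 2069 genes changed, 829 up and 1240 down (limma, adjusted p under 0.05), of which 479 changed at least 2-fold and 78 at least 4-fold. After HEPHL1 the genes that rose most were GJA1 (31.2-fold), RGS22 (27.5-fold), a regulator of G-protein signalling, PGR, ARHGAP36 (12.8-fold), NPY1R (9.40-fold), the sulfatase SULF1 (8.15-fold), MGP (7.54-fold), the RNA-binding protein RBM24 (7.15-fold) and PKIB (7.04-fold). After DIO2 the largest falls were in ACTG2 (35.1-fold), the integrin ITGB6 (10.3-fold), the ectonucleotidase NT5E (9.90-fold), CALD1 (9.03-fold), the glypican GPC5 (7.32-fold), CNTNAP2 (7.24-fold), EPAS1 (6.91-fold), a hypoxia-inducible transcription factor, VGLL3 (6.86-fold) and the tight junction protein CLDN1 (6.48-fold). CNTNAP2 lost its call with zeros at the smallest value above 0 (limma adjusted p = 0.0953).

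Of the estrogen-induced list 24 of 31 members rose and none fell, or 25 and none adjusted over the list alone (median log2 change 0.90, camera adjusted p = 8.69e-25, and adjusted p = 0.0104 with an estimated correlation). MYB, a transcription factor, was 3.37-fold higher. In the estrogen-repressed list 6 of 12 fell and none rose, or 6 and 1 adjusted over the list alone (median -0.50, camera adjusted p = 0.0129, adjusted p = 0.522 with an estimated correlation). That call ended when the dimmest genes were left out (camera adjusted p = 0.0943). TGFB2 fell 5.05-fold, BMF 2.15-fold, EGFR 1.92-fold (limma adjusted p = 0.00487) and ERBB2 1.62-fold (limma adjusted p = 0.00829). BCL2, an inhibitor of apoptosis, rose 2.48-fold, to 836.8 ± 31.0 from 327.6 ± 15.9 (limma adjusted p = 0.00424). CYP19A1 measured 3967 ± 437.2 against 5316 ± 15.5 and missed the threshold (limma adjusted p = 0.0584), as did ESR1 at 929.5 ± 28.2 against 722.1 ± 29.2 (limma adjusted p = 0.1). CCND1 was 1.46-fold higher (limma adjusted p = 0.0116), a call that ended without continuous replicate 2 (limma adjusted p = 0.053) or 3 (limma adjusted p = 0.0508). MKI67 was 1.43-fold lower (limma adjusted p = 0.0346), and its call ended without any 1 of the 6 control and continuous arrays, with limma adjusted p from 0.0734 to 0.103.

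Both lists of lipid synthesis genes passed camera in continuous cells, though many members were not called. In the cholesterol list 9 of 18 members rose and none fell, or 13 and none adjusted over the list alone (median log2 change 0.76, camera adjusted p = 4.66e-07, adjusted p = 0.571 with an estimated correlation). STARD4, a sterol transporter, was 3.20-fold higher and CYP51A1 2.07-fold higher. In the fatty acid list 4 of 13 rose and none fell, or 7 and 1 adjusted over the list alone (median 0.66, camera adjusted p = 0.000104, adjusted p = 0.522 with an estimated correlation). These were ELOVL5 (2.41-fold), an elongase, the regulator SREBF1 (2.29-fold), ACSL1 (2.69-fold) and the desaturase SCD (2.73-fold). Of the NF-kB cytokine list 7 of 17 fell and none rose, or 8 and none adjusted over the list alone (median -0.33, or -0.21 with an offset of 50, camera adjusted p = 0.00128, adjusted p = 0.522 with an estimated correlation). RELB fell 2.12-fold and IL6 3.15-fold. DNA replication genes were lower as a list (median -0.19, camera adjusted p = 0.0462, adjusted p = 0.738 with an estimated correlation), although 1 of 27 members, MCM5, passed by itself and none adjusted over the list alone. MCM5 (limma adjusted p = 0.0477) lost its call without control replicate 1, 2 or 3, intermittent replicate 2 or continuous replicate 1, 2 or 3, with limma adjusted p up to 0.138. The list's call ended without control replicate 1 (0.0653) or 2 (0.0801), without continuous replicate 2 (0.052) or 3 (0.103), after quantile normalization (0.087) and without the dimmest genes (0.0989), all camera adjusted p.

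The remaining 21 lists did not pass camera. Among them fry called the mesenchymal (0.000753), BCL2 family (0.00135), ERBB (0.0185), immediate early (0.0222), luminal (0.0246), MAPK output (0.0432) and xenobiotic (0.0447) lists. Fry did not call the cholesterol (0.0593) and DNA replication (0.164) lists that camera called, all fry adjusted p. The interferon list had 1 of 28 members up (IFI27, 2.83-fold), 1 down and a median log2 change of 0.04 (camera adjusted p = 0.699). Its continuous arrays were spread, with list means of 0.60, 0.02 and 0.49 against 0.26 to 0.33 in control, so replicate 2 stood apart. None of the 8 antigen presentation genes was called. XBP1 rose 3.08-fold and AGR2 4.46-fold in the luminal list (2 up and 2 down of 15). BAK1 fell 3.37-fold in the BCL2 family (2 up and 4 down of 15). FN1 fell 5.15-fold and SNAI2 4.07-fold in the mesenchymal list (0 up and 3 down of 13), EGR1 fell 2.57-fold among immediate early genes (0 up and 3 down of 10) and CTSB fell 2.52-fold in the lysosome list (0 up and 3 down of 18). ABCC3, an efflux pump, fell 2.42-fold (0 up and 2 down of 10), and ACTA2, a smooth muscle actin, fell 2.46-fold among the stromal and endothelial markers (0 up and 2 down of 13), while no immune marker was called of 11. Members up and down were 2 and 2 of 18 for androgen targets, 0 and 3 of 20 for steroid metabolism, 0 and 3 of 13 for ERBB ligands and receptors, 0 and 1 of 17 for MAPK output, 4 and 4 of 18 for PI3K and IGF and 0 and 3 of 24 for mitosis. They were 4 and 1 of 18 for p53 targets, 2 and 1 of 18 for the unfolded protein response, 1 and 0 of 11 for basal and progenitor genes, 3 and 2 of 18 for hypoxia and glycolysis and 1 and 4 of 14 for xenobiotic and oxidative genes. Adjusted over the list alone, the counts that differed were 3 and 3 for luminal identity, 3 and 2 for androgen targets, 2 and 4 for steroid metabolism, 2 and 4 for MAPK output, 7 and 5 for PI3K and IGF, 5 and 1 for p53 targets, 1 and 3 for autophagy, 3 and 1 for the unfolded protein response, 1 and 3 for the mesenchymal list, 2 and 0 for basal genes and 1 and 3 for immediate early genes. The median and mean log2 change differed in sign for luminal identity (-0.10 and 0.09), androgen targets (-0.12 and 0.05) and stromal and endothelial markers (0.03 and -0.11). The count of changed genes depended on the fit: it was 3171 with trend and robust options. It was 1318 and 1161 without control replicate 1 or 2, and 1217, 1006 and 1103 without continuous replicates 1, 2 or 3, fits with fewer arrays.

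Against the shared control, 1188 genes changed in the same direction in both treated groups, 401 up and 787 down. Independent lists of these lengths would share 68.5 rising and 149.3 falling genes. Simulated data in which no gene changed, with controls shared by both comparisons, gave 0.01 shared genes on average and at most 1. Hardly any gene is called in such data, so this count does not show how many shared calls the common controls add. PGR, GREB1, TFF1, PKIB, GJA1, NPY1R and MGP were among the shared rises and DIO2, ACTG2, CALD1, BMF, SNAI2 and FN1 among the shared falls. Across genes, which are not independent replicates, the log2 changes of both treatments correlated at 0.64, against 0.50 in the simulation. Their covariance was 0.14 against 0.02 in the simulation, whose 2 comparisons also shared their controls, a difference of 0.12. Splitting 3 controls would leave fewer than 2 arrays on a side, so part of the excess of shared genes over independent lists may come from the shared controls. The shared count was 775 and 691 without control replicate 1 or 2, and 758, 678 and 700 without continuous replicates 1, 2 or 3.

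The third comparison sets the 2 schedules against each other, with drug concentration, testosterone and total weeks alike. Time on the drug differed, since intermittent cells had weeks off it, and the labels do not say whether they were on it at harvest. HEPHL1 was 82.1-fold lower in intermittent than in continuous cells, at 5.66 ± 7.50 against 1703 ± 170.4 (limma adjusted p = 3.28e-07), and RGS22 was 25.2-fold lower (limma adjusted p = 1.24e-07). PIP, a secreted protein induced by androgens and prolactin, was 14.6-fold higher in intermittent cells (limma adjusted p = 0.000591), and the complement genes CFB and C3 were 14.4-fold and 6.94-fold higher. Of the interferon list 15 of 28 members were called lower in intermittent cells, and of the DNA replication list 7 of 27 were called higher and 1 lower. Neither list passed camera with an estimated correlation (adjusted p = 0.484 for each). Estrogen targets differed in part: PKIB (3.26-fold, limma adjusted p = 0.000116), MYBL1 (2.79-fold, limma adjusted p = 0.000243) and RAPGEFL1 (2.60-fold, limma adjusted p = 0.000292) were higher in intermittent cells, while PGR (limma adjusted p = 0.0776), GREB1 (limma adjusted p = 0.627) and TFF1 (limma adjusted p = 0.0792) did not pass.

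Between the schedules 2304 genes differed, 1106 higher and 1198 lower in intermittent cells (limma, adjusted p under 0.05), 451 of them at least 2-fold and 47 at least 4-fold. Of the 2304, 1120 were called against control in intermittent cells alone, 367 in continuous cells alone, 277 in both and 540 in neither. Besides PIP, CFB and C3, the genes highest in intermittent cells were TXNDC8 (13.6-fold), F13A1 (13.4-fold), the iron-binding protein LCN2 (10.9-fold), the transglutaminase TGM2 (10.7-fold), FLRT3 (7.17-fold), RIMS2 (6.81-fold) and the semaphorin SEMA3D (5.94-fold). Besides HEPHL1 and RGS22, the genes lowest in them were PCDHB2 (19.8-fold), CDH2 (11.9-fold), PLS3 (11.4-fold), the calcium-binding protein CALB2 (11.3-fold), CT83 (9.75-fold), the histone gene H4C4 (7.47-fold), CCDC85A (7.13-fold) and QPRT (6.51-fold), an enzyme of NAD synthesis. With zeros at the smallest value above 0, PIP (limma adjusted p = 0.15) and CDH2 (limma adjusted p = 0.0652) lost their calls. H4C4 belongs to a family of near-identical histone genes, so its probes may also report its copies.

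The interferon list was the most shifted: 15 of 28 members were lower and none higher, or 23 and none adjusted over the list alone (median log2 difference -1.16, camera adjusted p = 7.43e-11, but adjusted p = 0.484 with an estimated correlation). OASL was 2.48-fold lower and OAS1, a sensor of viral RNA, 2.94-fold lower. ISG15 was 2.33-fold lower and IFIH1 2.40-fold lower, and both calls ended without continuous replicate 1 (limma adjusted p = 0.058 and 0.0626). Without intermittent replicate 3, the lowest array, the median was -0.76. In the antigen presentation list TAP2, ERAP1, TAP1 and TAPBP were lower, 4 of 8, or 5 adjusted over the list alone (camera adjusted p = 0.00822, adjusted p = 0.484 with an estimated correlation). Whether these genes shifted together with their neighbours in the genome was not tested. Continuous replicate 2 stood apart in both lists, with list means of 0.02 for interferon and -0.14 for antigen presentation, against 0.49 or more and 0.27 or more in the other continuous arrays. TAPBP's call ended without continuous replicate 1 or 3, with limma adjusted p up to 0.064.

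**Figure D2:**
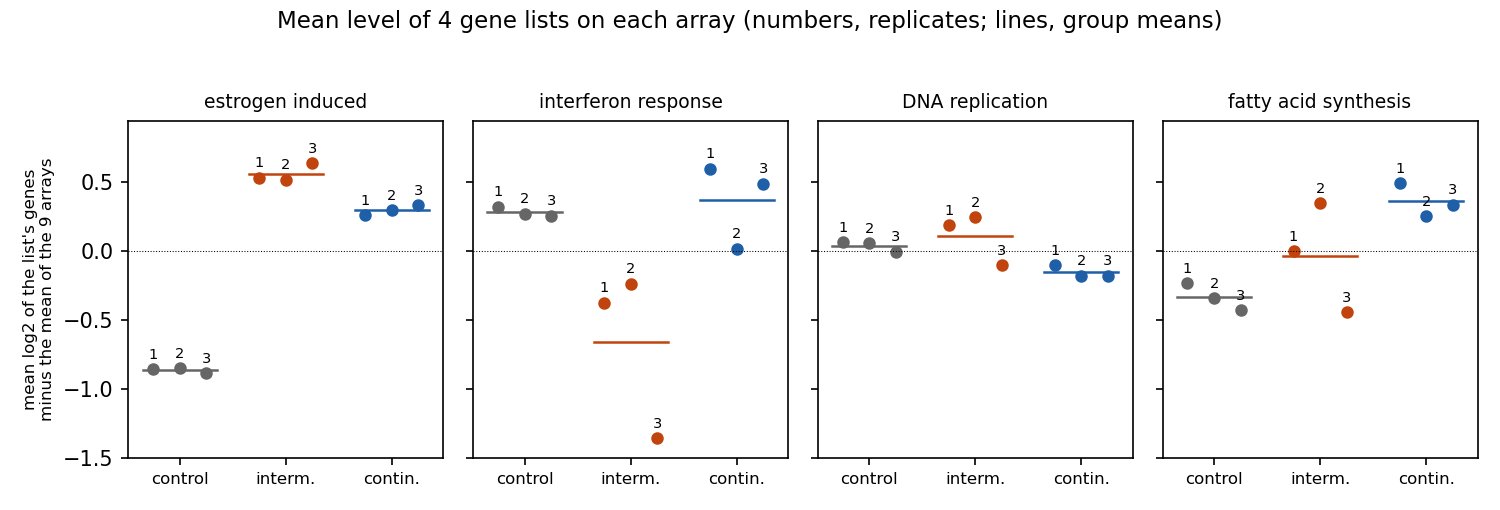
Mean log2 value of the genes of 4 lists on each array minus the mean of the 9 arrays (vertical axis), for control, intermittent and continuous cells, with replicate numbers at the points and lines at group means. Estrogen-induced genes lie above 0 on all 6 treated arrays, and intermittent replicate 3 lies apart from the other intermittent arrays in the interferon list at -1.36.

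The DNA replication list was called higher in intermittent cells, with 7 of 27 up and 1 down, or 12 and 1 adjusted over the list alone (median log2 difference 0.36, camera adjusted p = 0.000861, adjusted p = 0.484 with an estimated correlation). GINS2 was 1.78-fold higher, RFC4 1.63-fold, MCM5 1.59-fold and MCM7 1.46-fold. Intermittent replicate 3 did not share this shift: its list mean was -0.10, as in continuous cells (-0.18 to -0.10), against 0.19 and 0.25 in the other intermittent arrays. The groups overlapped (exact permutation p = 0.2, n = 3 and 3). Mitosis genes were higher as a list with 2 of 24 up, NUSAP1 and TOP2A, the same adjusted over the list alone (camera adjusted p = 0.00358, adjusted p = 0.484 with an estimated correlation). The mitosis call ended without intermittent replicate 2 (camera adjusted p = 0.114), and TOP2A's ended without intermittent replicate 1 or 2 or any 1 continuous array, with limma adjusted p up to 0.101. Intermittent replicate 3 had the lowest mitosis mean of its group, -0.12 against 0.14 and 0.38, within the range of continuous cells (-0.18 to -0.09). MKI67 did not differ detectably (limma adjusted p = 0.882). Targets of p53 were lower, 5 of 18 down and 1 up, or 6 and 2 adjusted over the list alone (median -0.34, camera adjusted p = 0.00822, adjusted p = 0.484 with an estimated correlation), with CDKN1A, an inhibitor of the cell cycle, 1.93-fold lower and CCNG1 1.84-fold lower. Without intermittent replicate 3, whose list mean was 0.03 against -0.20 and -0.23 in the others, their median was -0.51.

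Estrogen-induced genes were somewhat higher in intermittent cells, 11 of 31 up and 3 down, or 14 and 4 adjusted over the list alone (median 0.19, camera adjusted p = 0.00482, adjusted p = 0.45 with an estimated correlation). PKIB was 3.26-fold and MYBL1 2.79-fold higher, while HSPB8, a small heat shock protein, was 3.46-fold lower. Xenobiotic and oxidative response genes were higher, 5 of 14 up and 2 down, or 7 and 2 adjusted over the list alone (median 0.42, camera adjusted p = 0.0075, adjusted p = 0.45 with an estimated correlation), with a median of 0.73 without the dimmest genes. The reductases TXNRD1 and NQO1 were 3.60-fold and 2.38-fold higher and CYP1B1, an estrogen hydroxylase, 2.38-fold higher. MAPK output genes were higher, 4 of 17 up and none down, the same adjusted over the list alone (camera adjusted p = 0.00822, adjusted p = 0.45 with an estimated correlation), with SPRED1, an inhibitor of the pathway, 2.25-fold higher. The arrays were uneven in this list, with means of 0.03, 0.30 and 0.04 in intermittent and -0.04, -0.30 and -0.34 in continuous cells. Androgen targets were higher, 5 of 18 up and none down, the same adjusted over the list alone (camera adjusted p = 0.0126, adjusted p = 0.45 with an estimated correlation), among them PIP, STEAP4 (2.62-fold) and ZBTB16 (2.35-fold). STEAP4, listed at 0 on 1 continuous array, lost its call with a floor of 16 (limma adjusted p = 0.126) and with zeros at the smallest value above 0 (limma adjusted p = 0.0508). ZBTB16's call ended with an offset of 1 (limma adjusted p = 0.197) and with zeros at the smallest value above 0 (limma adjusted p = 0.719). Without the dimmest genes neither list passed (camera adjusted p = 0.103 for MAPK output and 0.764 for androgen targets, whose median log2 difference went from 0.14 to 0.02), and androgen targets also missed the threshold with a floor of 16 (0.0725) and with zeros at the smallest value above 0 (0.111).

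Fatty acid synthesis genes were lower in intermittent cells, 3 of 13 down and none up, or 5 and none adjusted over the list alone (median -0.47, camera adjusted p = 0.00822, adjusted p = 0.484 with an estimated correlation), with ELOVL5 1.77-fold lower and FADS2 2.27-fold lower. Without intermittent replicate 3 the median was -0.19 and the call ended (camera adjusted p = 0.102). The list means of the intermittent arrays were 0.00, 0.35 and -0.44, against 0.26 to 0.50 in continuous cells. The unfolded protein response list was lower by a narrow margin, 4 of 18 down and 1 up, or 5 and 1 adjusted over the list alone (median -0.30, camera adjusted p = 0.0478, adjusted p = 0.621 with an estimated correlation). DNAJB9, a chaperone of the endoplasmic reticulum, was 3.04-fold lower and PDIA4 2.19-fold lower, while XBP1 was 1.63-fold higher. This call ended without control replicate 2 (0.0556) or 3 (0.0537), intermittent replicate 1 (0.447) or 2 (0.147) or continuous replicate 1 (0.107) or 3 (0.0661), all camera adjusted p, and in 5 other settings. Its median was -0.12 without intermittent replicate 1 and -0.49 without intermittent replicate 3, whose list mean of 0.35 lay above those of continuous cells (0.07 to 0.26).

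**Figure D3:**
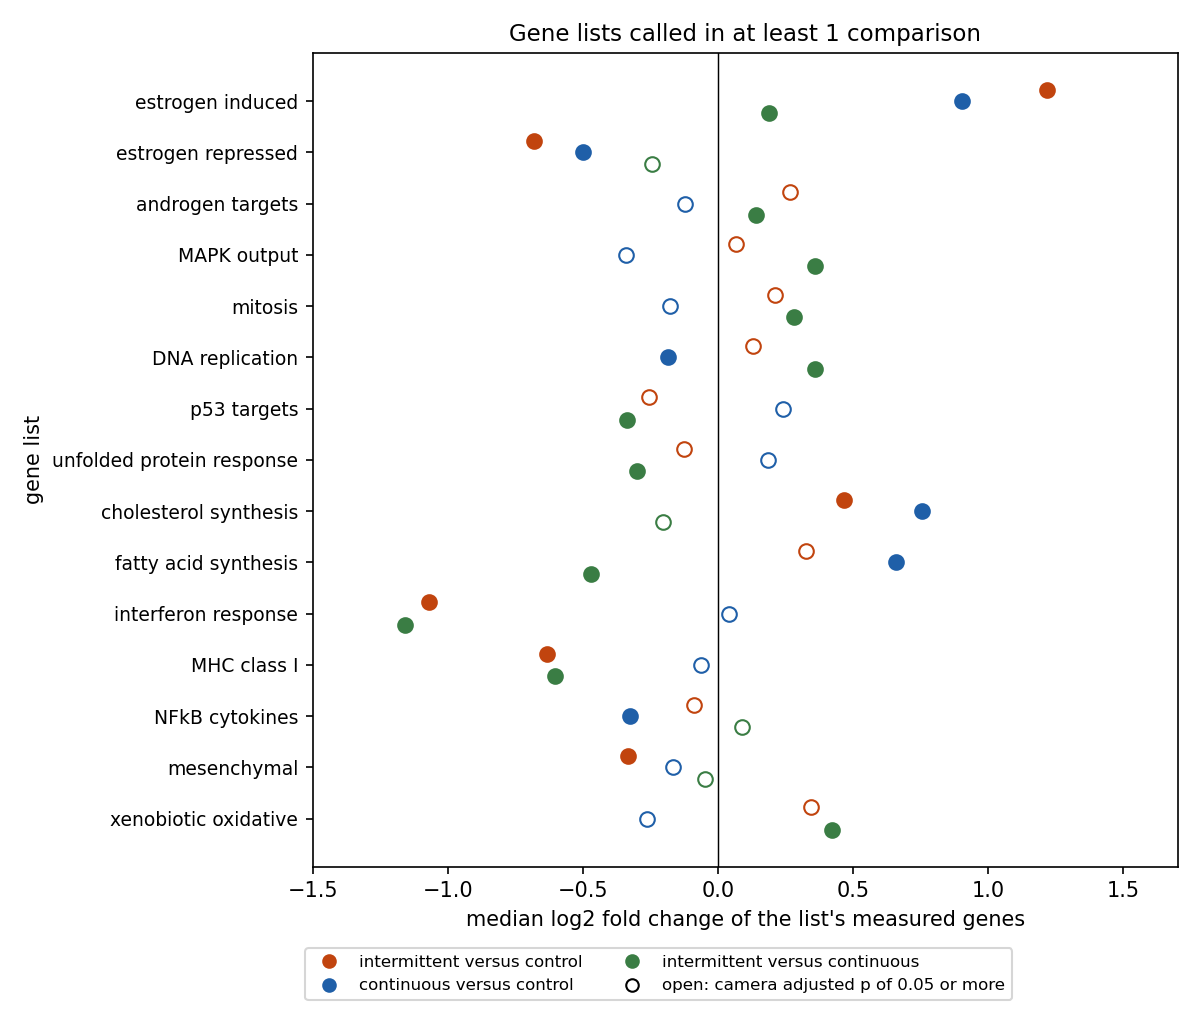
Median log2 fold change (horizontal axis) of the measured genes of each list called in at least 1 comparison, with colours for the 3 comparisons, filled points for lists past camera's adjusted threshold of 0.05 and open points for the others. The interferon list is at -1.07 and -1.16 in the comparisons of intermittent cells and at 0.04 for continuous cells against control.

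The other 16 lists did not pass camera between the schedules. Among them fry called the mesenchymal (0.00157), BCL2 family (0.00659), steroid metabolism (0.0351) and immune marker (0.0479) lists. Fry did not call the fatty acid (0.095), mitosis (0.114) and unfolded protein response (0.213) lists that camera called, all fry adjusted p. FN1 was 2.14-fold higher and TWIST1 4.03-fold lower in intermittent cells (mesenchymal, 1 up and 2 down of 13). AKR1C1, a hydroxysteroid dehydrogenase, was 3.78-fold higher (steroid metabolism, 4 up and 2 down of 20), ABCC3 3.60-fold higher and ABCG2 2.92-fold lower (efflux, 2 up and 3 down of 10). ICAM1 was 2.38-fold higher (NF-kB, 5 up and none down of 17), IGF1R 1.66-fold higher (PI3K and IGF, 4 up and 2 down of 18), SOX9 1.95-fold higher (basal and progenitor, 1 up and 2 down of 11) and PFKFB3, a regulator of glycolysis, 2.62-fold higher (hypoxia, 2 up and 1 down of 18). BMF was 2.44-fold lower and BAK1 1.79-fold lower (BCL2 family, none up and 4 down of 15). In the estrogen-repressed list 1 was up and 4 down of 12, in luminal identity 2 and 1 of 15, among ERBB ligands and receptors 1 and 0 of 13, in autophagy and lysosome 1 and 2 of 18, in cholesterol synthesis 0 and 1 of 18, among immediate early genes 0 and 1 of 10, among immune markers 0 and 0 of 11 and among stromal and endothelial markers 0 and 2 of 13. Adjusted over the list alone, the counts that differed were 5 and 3 for steroid metabolism, 4 and 4 for PI3K and IGF, 1 and 5 for the BCL2 family, 0 and 0 for cholesterol synthesis, 2 and 2 for basal genes, 2 and 2 for hypoxia and 4 and 3 for efflux. The median and mean log2 difference had opposite signs for PI3K and IGF (-0.03 and 0.02), and camera's direction for immediate early genes was down with a median of 0.03. CYP19A1 (limma adjusted p = 0.12), ESR1 (0.374), EGFR (0.721), ERBB2 (0.94), CCND1 (0.307) and BCL2 (0.0652) did not pass. No list kept its call with an estimated correlation in this comparison. The count of 2304 fell to 1329, 1393 and 1325 without continuous replicates 1, 2 or 3, fits with fewer arrays.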

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

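The offsets of 1 and 50, the floor of 16 and zeros at the smallest value above 0 were added after seeing the data, and the other alternatives were set before the data were examined. Of the results per gene under these alternatives, 5795 kept direction and side of the threshold, 404 lost a call, 27 gained one and 6 changed sign, and of the results per list 452 kept both and 54 lost a call. Of the counts, 155 stayed within 1.5 times the reported value and 25 did not. For continuous against control, eBayes with trend and robust options called 3171 genes (the cause was not tested). Requiring a 2-fold change left 836, 479 and 451 genes in the 3 comparisons (intermittent and continuous against control, then intermittent against continuous), and limma's treat against 1.2-fold 1430, 630 and 702, both stricter by construction. With an estimated correlation, which allows for correlation between a list's genes, camera called 1, 1 and 0 lists. Fry called 11 lists for continuous against control against 6 by camera, but the 2 tests ask different questions, so these counts are not alike. Without each array in turn, fits with fewer arrays, the counts were 2562 to 3283, 1006 to 2338 and 1325 to 2221 genes, 3255 to 4163 among the 3 groups, 678 to 1105 shared, and 4 to 10, 5 to 7 and 10 to 12 lists. Between intermittent and continuous cells, 3 log2 differences that were not called changed sign: ESR1 with the mean of its rows (0.0276), ERBB2 without an array (-0.1391 to 0.0503, above 0 also at 0.021 and 0.0025) and MKI67 without an array (-0.0348 to 0.1705, below 0 also at -0.0041). The cause was not tested. The replicate numbers did not pair the arrays, since deviations of arrays with the same number correlated at -0.13 to 0.096, and 4 of 9 arrays correlated best with their own number. With a block for them the counts were 3182, 1592 and 1839. In simulated data with 200 of the brighter genes changed, 20% to 24% of 1.5-fold changes were recovered. Many more genes were called in the real data, which loosens the adjusted threshold. Genes called there had a median size of log2 change of 0.69 to 0.71. The simulated share therefore does not carry over to these data, and how many small changes were missed is not known.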

Other observations

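In this part, these tests were chosen after a result on the same question was seen: the shuffled gene order, the interferon difference without each array, and the split of falling genes after local medians were subtracted, with its shuffled orders. The genes named here and the windows of neighbouring genes were also chosen then. The other tests were set before their results were seen.

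Other splits of the same arrays were fitted. Of the 10 splits of the 6 arrays, 1 split, the real one, gave as many genes in each comparison: 3739 for intermittent against control, 2069 for continuous against control and 2304 for intermittent against continuous, with a highest other count of 0 in each. These 10 splits are too few for a share under 0.05. For the test across the 3 groups, 1 of 100 splits drawn from 280 gave as many genes, the real one, with 4424 against 683 for the highest other. A random grouping of these arrays can thus be excluded for that count. The splits cannot exclude chance differences between cultures, since nothing says that the replicates came from separate cultures.

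Against control, 58 genes were called in opposite directions in the 2 treated groups, and all 58 were also called between the schedules. The second count follows from the first, since the schedule difference joins 2 opposite called changes that share 1 standard error. The 18 higher in intermittent cells include S100A9 (log2 changes 1.18 in intermittent and -1.16 in continuous cells). The 40 lower in them include CALB2 (-1.30 and 2.20), CT83 (-2.45 and 0.83), CCDC85A (-1.48 and 1.36) and SLC6A14 (-1.67 and 0.77).

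Genes that lie side by side in the genome differed together between intermittent and continuous cells. Over 12268 genes placed in order, the log2 differences of neighbours correlated at 0.252, above the highest of 100000 shuffled orders (0.0415, p = 1e-05, the smallest these shuffles can give). Of 296 windows of 40 genes, 44 lay beyond a limit set by 1000 shuffles, 33 lower and 11 higher in intermittent cells. In 95% of the shuffles no window at all lay beyond that limit. Neighbours also correlated in the comparisons with control, at 0.186 for intermittent and 0.135 for continuous cells. There 31 and 14 windows lay beyond their own limits. The window from COQ8A to NTPCR had a median log2 difference of -0.62, with 38 of 40 genes below 0, and a median of -0.69 for intermittent but -0.04 for continuous cells against control. The window from HARS1 to RBM27, which holds the PCDHB genes, had -0.54 and that from ZMAT3 to TRA2B 0.46. Trends of single arrays do not account for it, as deviations of arrays from their group means gave 3.66% of the neighbour covariance. Shared probes in families of related genes were tested by leaving out such neighbours, and the correlation was still 0.241. Co-regulation of a few adjacent genes would not reach far, and genes 30 places apart still correlated at 0.124. It is thus not the whole cause, but the drop from 0.252 for direct neighbours leaves a part for it open. A candidate explanation is a difference in DNA copy number between the cultures, for example from outgrowth of different subclones over 14 weeks. DNA was not measured, so this stays a hypothesis, and a technical effect shared by all arrays of a group or broad chromatin changes stay open. Of all genes in windows 14.9% lay in shifted windows, and of those called between the schedules 30.8%. The windows were chosen on the same differences, so a higher share among called genes is expected.

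The lower interferon list in intermittent against continuous cells was not explained by such windows: after the median of the 40 surrounding genes was subtracted its median was -1.11, against -1.16 before. Dim genes did not account for it, as its 25 members brighter than the median gene had a median of -1.2. All 28 members lay below 0. The difference of the groups' list means was -1.03 (95% interval -1.82 to -0.24). Its interval pools the spread within all 3 groups. SDs of the list means were 0.0345 in control, 0.612 in intermittent and 0.308 in continuous cells, so the even control arrays narrow it. Intermittent and continuous arrays did not overlap (exact permutation p = 0.1, the smallest that 3 against 3 arrays can give). Without each array in turn the difference lay between -1.24 and -0.68, so no 1 array removed it. Without intermittent replicate 3, the lowest array, it was -0.68 (-1.15 to -0.20). That interval also rests on the control arrays, so it does not settle whether that array was the sole source. Without continuous replicate 1 the interval reached 0.0633 and without continuous replicate 3 it reached 0.0407, with differences of -0.91 and -0.96. For these arrays the interval, from fewer arrays, leaves the question open. With an estimated correlation between its genes the list did not pass (camera adjusted p = 0.484). Whether the intermittent cells were collected on or off the drug, a different state of the cultures at harvest and the schedule itself may each contribute, and these data do not separate them. For the antigen presentation list the median of surrounding genes was not subtracted, so a shift of the regions that hold its genes stays open.

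More genes fell than rose in intermittent cells against control, 59.3% of those called. The share was 59.9% in continuous cells against the same controls, and 52.0% between the schedules. For intermittent and continuous cells it was 55.48% and 54.25% without control replicate 1, 58.24% and 59.78% without replicate 2, and 62.37% and 63.92% without replicate 3. Dim genes did not account for the excess in intermittent cells, as 59.2% fell when they were left out. Scaling between arrays stays open, since the share depended on the centring. It was 58.5% after quantile normalization and 64.2% after median centring on all rows. It was 52.8% to 53.7% when local medians along 20 shuffled gene orders were subtracted from 12268 placed genes, of which 59.2% of those called fell before. These orders hold no regions, so quantile normalization alone was too narrow a test of scaling. With the real gene order the share was 52.3%, close to the shuffled orders, so this test says nothing about regions of neighbouring genes. The excess may thus come from scaling or from the control arrays that both comparisons share. It may also follow from the drug, testosterone, 14 weeks of culture or a difference in hormone stripping before harvest, which the labels leave unclear.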
